A study of Mus musculus with 6 samples.

How the data were processed

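Samples were total RNA of mouse neural stem cell cultures, 1 Affymetrix array per culture. Per the labels, targets were biotin-labelled with whole-transcript kits. The deposited values are log2 signals per probe set, made with Affymetrix Expression Console and RMA per the submitters' processing notes, and the versions and settings of both are not given in the sources used here. RMA corrects background, equalises the distribution of signal over arrays and summarises probes, so a change shared by most genes would be hidden. The genome build behind the probe sets is not given in the sources used here, so no positions are printed. Low signals hold background, and no detection calls were used, so differences of dim genes can be understated.

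Arrays were grouped by the virus that titles and transduction labels give, with 3 arrays per virus, and by the cell line number in the titles. Another label field, the description, carries marks that run the opposite way in line 8 from lines 2 and 7. Titles and transduction labels give every array the same virus and were used, and an exchange of the line 8 labels was run as an alternative. With the labels used, the Ad-Cre minus Ad-GFP differences of line 8 correlated across genes with those of line 7 at r = 0.556 and of line 2 at r = 0.397, and lines 2 and 7 at r = 0.371. An exchange turns the sign of the line 8 correlations. Genes are not independent replicates. All 6 array columns were used. The table has 269751 probe sets, several per gene. GEO's platform annotation gives 1 gene symbol to 233753 of them, several to 5106 and none to 30892. Probe sets with 1 symbol were summarised to 23152 genes by Tukey median polish (at most 20 iterations), with a median of 8 probe sets per gene, and the other probe sets entered only the tests per probe set. Gene symbols are those of the annotation, which can be old. Of 831 list members, 43 had no probe set of their own and 8 were matched through a synonym in a gene table of the mouse assembly GRCm38.p6.

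Ad-Cre was compared with Ad-GFP by limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0 read the labels), with the cell line as a block and the virus as the effect, moderated variances with a trend on mean signal, two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05. The block was chosen from the series design, in which each of 3 cell lines received each virus. As a check of the pairing, the deviations of arrays from their virus mean were correlated across genes. Arrays of the same number correlated at 0.226, 0.163 and 0.333 for lines 2, 7 and 8, and arrays of different numbers between -0.227 and 0.003. Deviations within a virus cancel out for each gene, so positive values for the same number by themselves pull the others negative. The replicates are separate cell lines, so the p-values measure the spread of the virus effect between lines, from 1 culture per line and virus. Whether lines come from separate embryos is not stated in the labels. Kdm5d, a gene of the Y chromosome, averaged 5.74 in line 7 and 10.45 in lines 2 and 8. Xist, of the inactive X chromosome, read 13.82 and 13.58 in line 7 and at most 7.91 elsewhere. These values argue against 1 embryo shared by line 7 and another line, and leave lines 2 and 8 open. The same model tested differences between lines (moderated F test) and each probe set.

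Gene lists, 33 of them tested, were compared with all other genes by camera at a preset inter-gene correlation of 0.01, adjusted over the lists, for lists with at least 5 measured genes. An estimated correlation and fry, which tests a list without reference to other genes, were run beside it. All 5 calls of camera at the preset correlation were lost with the estimated one. Many of the 33 lists then shared an adjusted p of 0.727, so that value does not tell those lists apart. Where a call with 1 line left out is set beside such a value, both the arrays and the test differ. The estimated correlation was 0.987 for cell cycle, 0.773 for cholesterol synthesis and 0.0559 for immediate early genes. For p53 targets and oligodendrocyte markers it was -0.0048 and -0.0462, below the preset. A higher correlation between genes does not account for the loss of those calls. Their unadjusted camera p went from 1.03e-09 to 0.0206 and from 2.45e-06 to 0.0361. With an estimated correlation camera tests on the 2 residual degrees of freedom of the fit, which leaves little power over 33 lists. A call lost this way does not by itself show that correlated genes had made it. The genes to name were, in each direction, the 10 with the largest difference among genes past the threshold and of the same direction in all 3 lines. Places left were filled from genes with an unadjusted p under 0.01 and the same direction in all 3 lines, and here these filled all places. Predicted and family symbols were passed over. Idh1, Idh2, Nes, Sox2, Gfap, Mki67 and Cdkn1a were always named, as were up to 4 genes per list with the lowest p, and for lines up to 10 genes past the threshold. Opalin, Bub1, Top2a, Cdt1, E2f1, Serpina3n, Sparcl1, Spry4, Dusp6, Etv5 and Tnfrsf10b were named after their values were seen. The design, gene lists, naming rule and most alternatives were fixed before the data were examined.

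The gene test was tested on simulated data with variances drawn from the prior of the real fit and 200 changed genes among 23152. It called 60% of genes changed by 1 log2 unit and 96% of those changed by 2 log2 units at the adjusted threshold, with 4 false calls, and 4.90% of unchanged genes had an unadjusted p under 0.05. A list raised by 0.5 log2 units was called in 20 of 20 draws, with 1 call among 640 unchanged lists. Simulated genes varied independently of each other, with the same variance in every line. These rates therefore do not carry over to lists of correlated genes or to a line that departs from the others. Median polish of simulated probe sets gave a median error of -0.12 for a difference of 2 log2 units.

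Alternatives were the fit without the block, the line as a random block, the line 8 exchange, filters on dim genes, further normalizations (quantile, median centring, cyclic loess), other gene summaries (mean or brightest probe set), other variance models, and each line left out. A threshold of 0.10 and array quality weights were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.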

Results

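Expression was measured in neural stem cells from the cortex of mouse embryos at embryonic day 14.5. Such cells divide in culture and can give rise to neurons, astrocytes and oligodendrocytes. The study used 3 cell lines, numbered 2, 7 and 8. One culture of each line received an adenovirus with Cre recombinase (Ad-Cre), an enzyme that recombines DNA and here turns on mutant IDH. Another culture of the line received an adenovirus with green fluorescent protein (Ad-GFP), the control. Since 0 arrays carry Cre and no mutant allele, effects of Cre itself and of the mutant enzyme cannot be told apart in any comparison below. Both viruses were given at 100 MOI (infectious units per cell), and the cells were washed after 24 hours. The mutation in the series title is IDH1 R132H, a change in isocitrate dehydrogenase 1 that is frequent in gliomas. Each culture was read on 1 Affymetrix array, which gave 3 Ad-Cre and 3 Ad-GFP arrays and log2 signals for 269751 probe sets. These were summarised to 23152 genes. Median probe set signals lay between 8.38 and 8.43 on the 6 arrays. The number of arrays limits the precision of every value.

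Total Idh1 transcript did not differ between the viruses beyond the spread between lines. Idh1 read 12.65 ± 0.11 (SD, n = 3) on the log2 scale with Ad-GFP and 12.68 ± 0.29 with Ad-Cre, a difference of 0.03 ± 0.10 (SE; limma adjusted p = 0.917). In line 2 it read 12.78 with Ad-GFP and 12.95 with Ad-Cre, in line 7 it read 12.60 and 12.38, and in line 8 it read 12.58 and 12.72. None of the 12 Idh1 probe sets was higher in all 3 lines or lower in all 3, and their mean differences ranged from -0.17 to 0.11. The sources used here do not say whether any probe set tells the mutant allele from the normal one, so this level does not check that Cre had acted. Idh2, the mitochondrial isocitrate dehydrogenase, was higher by 0.46 ± 0.10 (SE; adjusted p = 0.187), in all 3 lines. The neural stem cell genes Nes and Sox2 differed by 0.08 ± 0.15 and -0.04 ± 0.13 (SE), with adjusted p of 0.849 and 0.916.

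The next comparison asked which genes differed between Ad-Cre and Ad-GFP within the lines. The 10 genes named in each direction had the largest differences among those with an unadjusted p under 0.01 and the same direction in all 3 lines, with predicted and family symbols passed over. The largest of these differences were lower signals with Ad-Cre, led by Pla2g7, Luzp2 and Tnr. Pla2g7, a secreted phospholipase that hydrolyses platelet-activating factor, was 21.7-fold lower, at -4.44 ± 0.65 log2 units (SE, n = 3 lines; adjusted p = 0.103), with the smallest difference in line 8 (-5.74, -5.13 and -2.45 in lines 2, 7 and 8). Tnr, an extracellular matrix protein of the brain made by oligodendrocyte-lineage cells, was lower by -3.34 ± 0.23 (adjusted p = 0.0669), and Cdo1, which oxidises cysteine, by -3.06 ± 0.18 (adjusted p = 0.0669). Pdgfra and Gpr17, receptors that mark oligodendrocyte progenitors, read -2.72 ± 0.34 (adjusted p = 0.0939) and -2.86 ± 0.26 (adjusted p = 0.0803). The others named as lower were Luzp2 (-3.38), Fam5c (-3.09), Erbb4 (-2.73), a neuregulin receptor, B3gnt5 (-2.70), a glycosyltransferase, and Slc1a1 (-2.62), a glutamate transporter, with adjusted p between 0.0669 and 0.172.

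Among the genes named as higher with Ad-Cre, Cacna2d3, a calcium channel subunit, had the largest difference, 2.04 ± 0.41 log2 units (adjusted p = 0.170). Its size and rank rested on line 2, where Cacna2d3 read 3.29, and without line 2 it read 1.42, below Adamtsl3 and Grin2a among others. Rtn4rl1, a Nogo receptor homologue, was higher by 1.90 ± 0.28 (adjusted p = 0.102), and Nupr1, a stress-induced chromatin protein, by 1.83 ± 0.33 (adjusted p = 0.145). The NMDA receptor subunit Grin2a was higher by 1.80 ± 0.18 (adjusted p = 0.0919) and Nptx1, a pentraxin of synapses, by 1.62 ± 0.17 (adjusted p = 0.0919). Cdk6, a G1 cyclin-dependent kinase, read 1.72 ± 0.37 (adjusted p = 0.195). The others named as higher were Adamts12 (1.70), Adamtsl3 (1.66), Adcy2 (1.62), an adenylyl cyclase, and Syt9 (1.60), a synaptotagmin. Differences of this size with a higher p were left out, among them Serpina3n at 2.13 (4.06, 1.66 and 0.67 in lines 2, 7 and 8) and Sparcl1 at 1.64 (0.96 without line 2). Adamtsl3 rested on the dimmer of its 31 probe sets, since the brightest one read -0.0081.

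**Figure D1:**
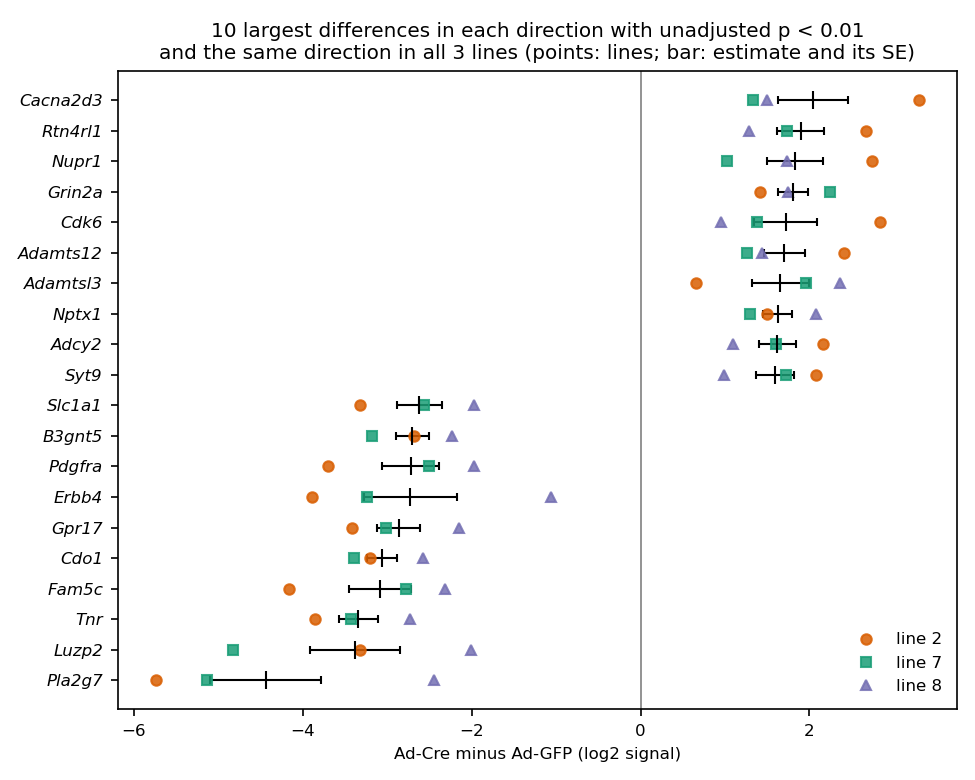
Ad-Cre minus Ad-GFP difference in log2 signal (x axis) for the 10 genes with the largest difference in each direction among those with an unadjusted p under 0.01 and the same direction in all 3 lines (y axis, predicted and family symbols passed over), with 1 point per cell line and a bar for the limma estimate and its SE. Every point of the upper 10 genes lies above 0 and every point of the lower 10 lies below 0, from -5.74 for Pla2g7 in line 2 to 3.29 for Cacna2d3 in line 2.

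None of these 20 genes passed the test across all genes, and none of the 23152 did. With limma and the line as a block, 0 genes had an adjusted p under 0.05, and the smallest adjusted p, 0.0669, was shared by 17 genes, among them Dcx, Dll3, Ugt8a and Klf4. At an unadjusted p under 0.05 there were 2923 genes, 1630 higher and 1293 lower with Ad-Cre, or 12.6% of genes where chance gives 5%. The direction was the same in all 3 lines for 8865 genes, 38.3% where chance gives 25%. The count depended on line 2 and on the model. Without the pair of arrays of line 2, 1211 genes passed, 615 higher and 596 lower, and all 20 genes above were among them. They had been chosen with these arrays included, so this is not independent evidence. In line 2, 80.6% of the 1211 genes went the same way. Without line 7 and without line 8 the count was 0, and in the fit without the line as a block it was 82, with 20 higher and 62 lower. The line as a random block gave 241 and the mean of probe sets in place of the median polish 73. With the virus labels of line 8 exchanged 0 genes passed and 418 had an unadjusted p under 0.05.

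Line 2 differed from the others in the size of its differences. Between its Ad-Cre and Ad-GFP arrays 1249 genes differed by more than 1 log2 unit, against 380 in line 7 and 252 in line 8. Gfap, the intermediate filament of astrocytes, was at 11.27 on the line 2 Ad-Cre array and between 7.48 and 8.33 on the other 5 arrays. Mki67, a marker of dividing cells, was at 10.10 there and between 12.43 and 12.84 on the others. Across genes, the line 2 Ad-Cre array correlated with the other arrays at r of 0.969 to 0.976, while those 5 correlated with each other at 0.988 to 0.996. These correlations are across genes, which are not independent replicates.

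**Figure D2:**
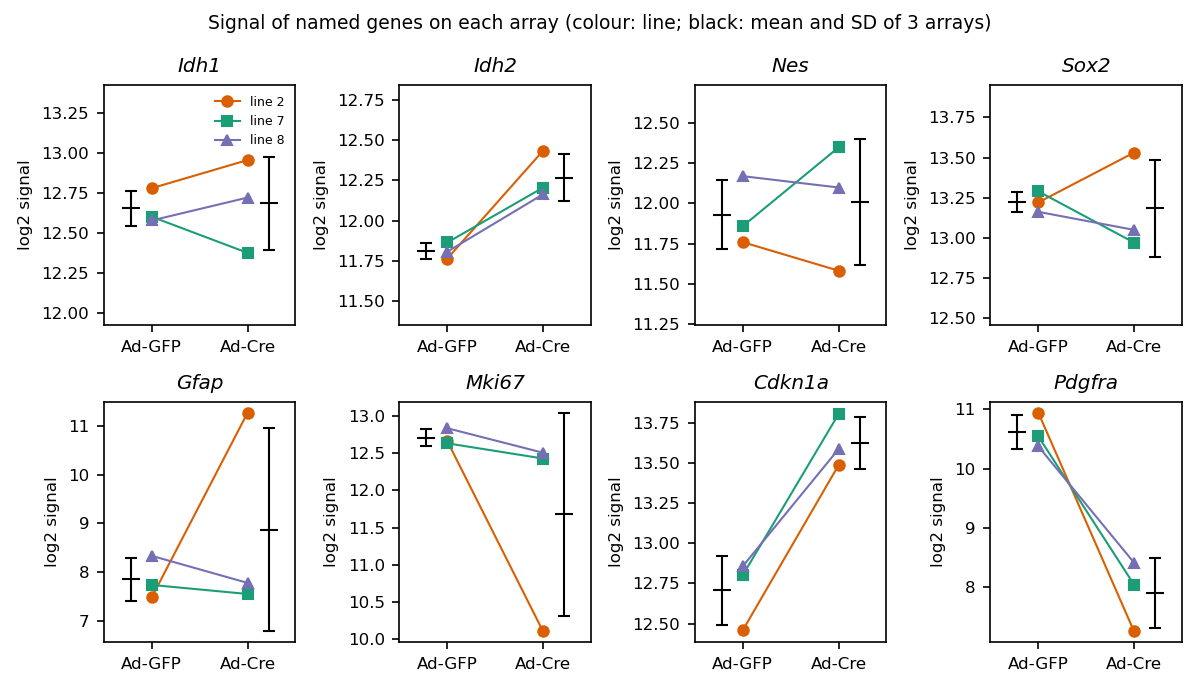
Log2 signal (y axis, whose range differs between panels) of 8 genes under each virus (x axis). Points joined by a line are the pair of arrays of one cell line, and black marks give the mean and SD of the 3 arrays of a virus. Cdkn1a was higher and Pdgfra lower with Ad-Cre in all 3 lines, while Gfap at 11.27 and Mki67 at 10.10 stood apart on the line 2 Ad-Cre array.

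Oligodendrocyte lineage markers fell as a group with Ad-Cre (camera adjusted p = 2.69e-05, preset correlation), with a median of -0.17 over 19 measured genes. The call was lost with an estimated correlation (adjusted p = 0.596), a test with little power on the 2 residual degrees of freedom of this fit. The shift rested on part of the list, whose mean was -0.53. At an unadjusted p under 0.05, 5 of the 19 genes were lower and 1 was higher. Adjusted over the list alone, 4 genes passed as lower and 1 as higher, and over all genes 0 passed. The 4 lower ones were Gpr17 and Pdgfra, given above, Ugt8a (-1.46 ± 0.10), which makes the myelin lipid galactocerebroside, and Bcas1 (-1.28 ± 0.14), a gene of early myelinating cells. Ugt8a depends on the probe sets used, since its brightest one read 0.23. The higher one was Opalin, a myelin protein, at 1.09. The list's line medians were -0.13, -0.18 and -0.16 in lines 2, 7 and 8, and 9 of its genes were lower in all 3 lines.

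Targets of the p53 tumour suppressor rose together with Ad-Cre (camera adjusted p = 1.69e-08), with a median of 0.41 over 27 measured genes and adjusted p = 0.596 with an estimated correlation. Adjusted over the list alone 17 genes passed, all higher, and over all genes 0 passed. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was higher by 0.92 ± 0.08 log2 units (SE; adjusted p = 0.0795 over all genes), or 1.89-fold. Phlda3, a repressor of Akt, read 0.93 ± 0.10 (adjusted p = 0.0919), Bbc3, a pro-apoptotic BH3 protein, 0.68 ± 0.10, and Ccng1, cyclin G1, 0.37 ± 0.06. The list medians were 0.34, 0.53 and 0.43 in lines 2, 7 and 8, and 18 of the 27 genes were higher in every line.

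Immediate early genes, which respond to growth factor and stress signals, also rose (camera adjusted p = 7.86e-05), with a median of 0.43 over 26 genes and adjusted p = 0.727 with an estimated correlation. The median was 0.22 in line 2, 0.39 in line 7 and 0.60 in line 8, and in line 2 11 of the 26 genes were lower, among them Spry4 at -1.80 and Dusp6 at -1.70. Adjusted over the list alone 10 passed, all higher, and 0 passed over all genes. The transcription factors Klf4 and Fosl2 were higher by 1.30 ± 0.10 (adjusted p = 0.0669) and 1.41 ± 0.16 (adjusted p = 0.0919), and Jun and Klf6 by 0.51 ± 0.08 and 0.44 ± 0.08. With the virus labels of line 8 exchanged, neither this list nor the oligodendrocyte or p53 list was called, and the immediate early median was -0.0034.

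Cell cycle genes fell as a group (camera adjusted p = 3.32e-09), with the largest differences in line 2. The call was lost with an estimated correlation (adjusted p = 0.727). The median over 39 genes was -2.26 in line 2, -0.09 in line 7 and -0.23 in line 8. All 39 were lower in line 2, while 15 were higher in line 7 and 9 in line 8. Ccnb2, a mitotic cyclin, read -3.65, -1.34 and -0.71 in lines 2, 7 and 8. Nusap1, Tpx2 and Birc5, which act on the mitotic spindle, read -2.48, -2.26 and -1.97 in line 2 and between -0.37 and -0.16 in the other lines. No gene of the list passed, over all genes or adjusted over the list alone. Without line 2 the list was called at the preset correlation with a median of -0.15 (adjusted p = 0.000246), but its genes went both ways, 27 lower and 12 higher. Ccnb2 (-1.03), Nusap1 (-0.33), Bub1 (-0.32) and Top2a (-0.31) then passed over all genes. Cdt1, which licenses replication origins, read 0.44 and the transcription factor E2f1 0.41, with adjusted p of 0.0706 and 0.0587. Genes of cholesterol synthesis fell too (camera adjusted p = 0.00436, and adjusted p = 0.727 with an estimated correlation), with a median of -0.15 over 20 genes. Their line medians were -0.54, -0.12 and 0.04 in lines 2, 7 and 8. Mvk, mevalonate kinase, read -0.45 ± 0.19, Fdft1, squalene synthase, -0.27 ± 0.13, Sc5d -0.29 ± 0.14 and Lss, lanosterol synthase, -0.29 ± 0.15, and 0 genes passed over all genes or adjusted over the list alone. Without line 2 that call was lost (median -0.03, adjusted p = 0.681), and it was kept in 13 of 18 alternatives.

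**Figure D3:**
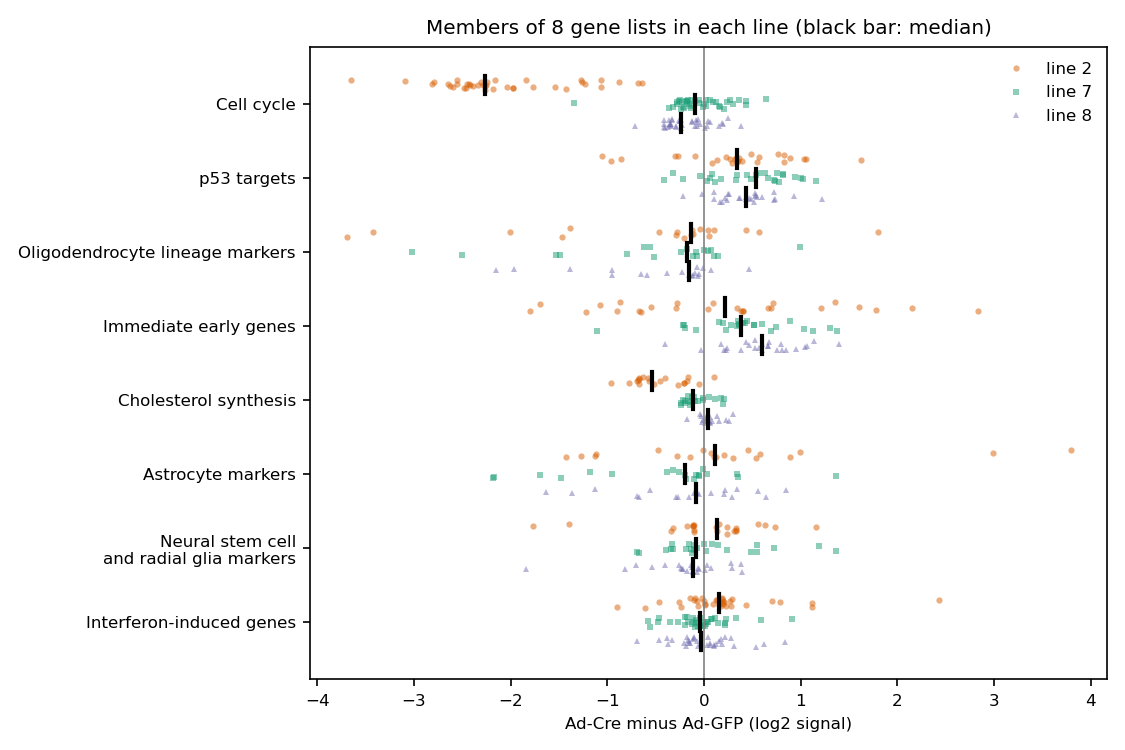
Ad-Cre minus Ad-GFP difference in log2 signal (x axis) of each measured gene in 8 gene lists (y axis), as 1 point per gene and line, with a black bar for the median of a list in a line. The cell cycle median was -2.26 in line 2 against -0.09 and -0.23 in lines 7 and 8, while the p53 target medians lay between 0.34 and 0.53.

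The other marker lists were not called. Of 20 astrocyte markers (median -0.05, camera adjusted p = 0.165), 5 passed as lower adjusted over the list alone and 2 as higher, with 0 over all genes. Aldh1l1, a folate enzyme, read -1.66 ± 0.19, the lipid carrier Apoe -1.31 ± 0.15, the GABA transporter Slc6a11 -1.15 ± 0.16 and the gap junction protein Gja1 -0.77 ± 0.15. Without line 2 the list was called as lower (adjusted p = 0.00216), at the preset correlation. With an estimated one and all 3 lines its adjusted p was 0.727. Of 29 neuronal markers (adjusted p = 0.794; median 0.08, mean -0.11, direction of the test down), 3 passed adjusted over the list alone. These were Dcx, a microtubule protein of young neurons, at -1.80 ± 0.09 (adjusted p = 0.0669 over all genes), Snap25, of the synaptic vesicle fusion machinery, at -2.45 ± 0.31, and the RNA-binding protein Elavl3 at -0.90 ± 0.13. Among 24 neural stem cell markers (median -0.04, adjusted p = 0.219), Prom1 read -1.31 ± 0.23, Msi1 -0.48 ± 0.10, Hes1 0.42 ± 0.10 and Hopx 0.71 ± 0.19, and 0 passed adjusted over the list alone. Without line 2 this list was called as lower (adjusted p = 0.0329), again against an adjusted p of 0.727 with an estimated correlation and all 3 lines.

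Markers of other cells that a cortical culture could hold had small medians, and no such list was called by camera. The median was 0.06 over 17 microglia and macrophage genes (adjusted p = 0.165), with Cd68 at 0.42 ± 0.15, and 0.11 over 14 endothelial genes (adjusted p = 0.146), with Emcn at 0.57 ± 0.14. Emcn was dim, with mean signals of 5.04 with Ad-GFP and 5.60 with Ad-Cre. The lower quartile of probe set signals was 6.6 on each array. The fry test, which asks only whether a list's genes move one way, called the microglia list (adjusted p = 0.0321) and the oligodendrocyte list, and no other. Among 20 fibroblast, meningeal and pericyte genes (adjusted p = 0.219; median 0.11, mean -0.03, direction of the test up), Acta2, smooth muscle actin, read -2.35 ± 0.48, Pdgfrb -0.61 ± 0.10 and Foxc1 0.83 ± 0.15. These 3 passed adjusted over the list alone.

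Of the signalling lists, TGF-beta and BMP targets had a median of 0.17 (camera adjusted p = 0.0571), with Id1 at 1.07 ± 0.19, Tgfb3 at 1.30 ± 0.29, Ltbp4 at 0.59 ± 0.11 and Skil at -0.70 ± 0.16, which passed adjusted over the list alone. Without line 7 this list was called as higher (adjusted p = 0.0458), and without line 8 too (adjusted p = 0.00874), both at the preset correlation. With an estimated correlation and all 3 lines its adjusted p was 0.727. In the Notch list (median -0.03, adjusted p = 0.222) the ligand Dll3 read -1.90 ± 0.11 (adjusted p = 0.0669 over all genes), the feedback inhibitor Nrarp -1.42 ± 0.19, Hey2 -0.60 ± 0.10 and the ligand Jag1 0.98 ± 0.15. Adjusted over the list alone 4 Notch genes passed as lower and 3 as higher, and without line 2 the list was called as lower (adjusted p = 0.0120, against an adjusted p of 0.727 with an estimated correlation and all 3 lines). In the Wnt list (median 0.13, adjusted p = 0.219) Lef1 read 1.49 ± 0.27, Fzd5 0.71 ± 0.10, Wnt7b -0.79 ± 0.13 and Sfrp2 -0.78 ± 0.13, all 4 passing adjusted over the list alone. In the NF-kB list (median 0.03, adjusted p = 0.642) Nfkbia read 0.90 ± 0.16, Nfkb2 0.54 ± 0.10 and Vcam1 -1.30 ± 0.18. Interferon-induced genes (adjusted p = 0.788) had a median of 0.02 and a mean of 0.05 while the test leaned down, with H2-K1 at -0.72 ± 0.11, Ifit2 at -0.50 ± 0.09 and Gbp2 at 1.29 ± 0.38. Gbp2 read 2.43, 0.59 and 0.84 in lines 2, 7 and 8. In the extracellular matrix list (median 0.04, adjusted p = 0.219) 7 of 36 genes passed as higher adjusted over the list alone and 3 as lower. Fn1, fibronectin, read 1.55 ± 0.28, its receptor subunit Itga5 1.27 ± 0.16, Mmp2 0.56 ± 0.10 and Timp3, an inhibitor of metalloproteinases, -2.01 ± 0.27.

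Stress lists leaned up without a call in the limma fit with the line as a block and the arrays as supplied. After quantile normalization or cyclic loess of the 6 arrays, the heat shock, amino acid starvation and TGF-beta lists were called as higher at the preset correlation. The amino acid starvation and unfolded protein list had a median of 0.13 (adjusted p = 0.0638), and adjusted over the list alone 8 of 27 genes passed as higher and 1 as lower. Vldlr read 0.91 ± 0.11, the amino acid transporter subunits Slc7a5 0.60 ± 0.09 and Slc3a2 0.31 ± 0.06, and Atf3 1.33 ± 0.28. Heat shock proteins had a median of 0.12 (adjusted p = 0.0638), with Hspa1b at 0.74 ± 0.18 and Bag3 at 0.92 ± 0.32 (1.89, 0.49 and 0.37 in lines 2, 7 and 8). Without line 2 both lists were called as higher, with adjusted p of 0.000496 and 0.00312 at the preset correlation. With an estimated correlation and all 3 lines each had an adjusted p of 0.727. NRF2 and glutathione genes (median 0.11, adjusted p = 0.165) had Srxn1 at 0.70 ± 0.14 and Hmox1 at 0.51 ± 0.11. Apoptosis regulators had a median of 0.02 (adjusted p = 0.634), with Apaf1 at 0.34 ± 0.10.

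Apart from cholesterol synthesis, given above, metabolic and chromatin lists were not called with all 3 lines. Idh and citric acid cycle enzymes had a median of -0.06 (adjusted p = 0.165), with Glud1, which makes 2-oxoglutarate from glutamate, at -0.33 ± 0.06, D2hgdh, which clears D-2-hydroxyglutarate, at -0.53 ± 0.13, and Idh2 as above. Without line 8 this list was called as lower (adjusted p = 0.0252), against an adjusted p of 0.727 with an estimated correlation and all 3 lines. The 2-oxoglutarate-dependent dioxygenases, a class of enzymes that D-2-hydroxyglutarate can inhibit, had a median of 0.02 and a mean of 0.01 while the test leaned down (adjusted p = 0.818), with Tet2 at -0.34 ± 0.09 and Plod2 at 0.41 ± 0.11. DNA methylation and chromatin repression genes had a median of -0.07 (adjusted p = 0.165), with Hdac1 at -0.21 ± 0.08. Hypoxia-inducible genes had a median of 0.11 (adjusted p = 0.219), with Adm at 1.13 ± 0.27, and glycolysis genes 0.02 (adjusted p = 0.734), with Pfkp at 0.99 ± 0.34. For oxidative phosphorylation the median was 0.02 and the mean -0.02 while the test leaned down (adjusted p = 0.634), with Cyc1 at 0.18 ± 0.07, and without line 2 the list was called as higher (adjusted p = 0.0329, against an adjusted p of 0.886 with an estimated correlation and all 3 lines). In none of these 6 lists did a gene pass adjusted over the list alone.

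Of the remaining 6 lists, ribosomal proteins had a median of 0.06 (adjusted p = 0.222), with Rpl30 at 0.54 ± 0.10, and were called as higher without line 2 (adjusted p = 0.0282, against an adjusted p of 0.727 with an estimated correlation and all 3 lines). The median of core histones was -0.13 (adjusted p = 0.165), with Hist1h2bm at 0.47 ± 0.10. Imprinted genes had a median of 0.12 (adjusted p = 0.477), and 4 passed adjusted over the list alone, namely Dlk1 (0.67 ± 0.09), Grb10 (0.64 ± 0.10), Igf2r (0.64 ± 0.11) and Nnat (-1.43 ± 0.24). Hox genes had a median of 0.08 (adjusted p = 0.146), with Hoxa4 at 0.33 ± 0.11. Dorsal forebrain patterning genes had a median of 0.15 and a mean of -0.03 while the test leaned up (adjusted p = 0.718). Otx2 read -2.32 ± 0.38 there and passed adjusted over the list alone, and Emx2 read 0.80 ± 0.22. Ventral patterning genes had a median of 0.07 (adjusted p = 0.483), with Dlx6 at 0.47 ± 0.14.

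The lines themselves differed in genes of the Y chromosome. Kdm5d, a histone demethylase gene, averaged 10.45 in line 2, 5.74 in line 7 and 10.45 in line 8 (limma F test, adjusted p = 0.0237), and Uty averaged 10.003, 5.32 and 9.98 (adjusted p = 0.0237). No other gene passed, while 1140 had an unadjusted p under 0.05. Xist, the RNA that coats the inactive X chromosome, read 13.82 and 13.58 in line 7 and between 6.45 and 7.91 on the other 4 arrays. By Kdm5d, Uty and Xist, line 7 read as female and lines 2 and 8 as male. Without line 7 the count of genes that differed between lines was 0, without line 8 it was 1, and without line 2 it was 37.

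Probe set by probe set, the comparison of Ad-Cre with Ad-GFP gave no call either. With limma 0 of 269751 probe sets had an adjusted p under 0.05 and 28950 had an unadjusted p under 0.05, or 10.7%. In the fit without the line as a block 67 passed, 2 higher and 65 lower.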

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

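Of the tests below, those on matched random lists of cell cycle and p53 genes and the one without line 2 were planned, and the others, on other cell types, astrocyte genes and Cre itself, were chosen only after the result was seen.

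Gfap was higher with Ad-Cre by 3.79 log2 units in line 2 and lower in line 8, at -0.56, and this difference between lines was not tested, since each has 1 array per virus. The cell cycle genes had a median of -2.26 in line 2, and a loss of signal from genes of that level is argued against by 10000 random lists matched on signal, whose central range was -0.18 to 0.06 and among which the list lay at percentile 0. For microglia, endothelial or fibroblast-type cells, the largest of the 3 marker list medians was 0.21 in line 2. The markers went both ways there, with 12 microglia genes higher and 5 lower, 11 and 3 endothelial genes, and 16 and 4 fibroblast-type genes. Medians of such lists on 1 array do not decide whether some of these cells were present. A wider astrocyte programme stays open, since the astrocyte markers other than Gfap had a median of 0.10 (percentile 93.1) but went both ways, 11 higher and 8 lower, with Sparcl1 at 2.99 and S100b at 0.997 against Aldh1l1 at -1.43 and Apoe at -1.11. A culture of line 2 that had left the cell cycle, whether through the virus, the mutant enzyme or its state at harvest, remains a hypothesis that 1 array leaves open.

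Probe sets that the annotation gives to several genes entered no gene value, and adjusted among the 5106 of this kind, 6 passed. Those with signal above the controls were probe sets 17421386 and 17421448, with identical values and a rise of 2.30 log2 units, and 17421389, which rose by 2.499. The first 2 were given to 1700029I01Rik, Gm13251 and Gm13139, and 17421389 to 1700029I01Rik and Gm13251. Those that fell were 17396864 (-2.52), given to Sox2ot and Mir1897, and 17226437 (-1.66) and 17226438 (-1.27), both given to Gpr39 and Lypd1. Because genes are shared, the 6 probe sets are not 6 separate findings. Among all probe sets none of them passed, with adjusted p of 0.139 to 0.142.

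The rise of p53 targets with Ad-Cre had a median of 0.41, at percentile 100 of random lists matched on signal, so an effect of normalization on genes of that level is argued against. The line 2 Ad-Cre array alone is argued against by the fit without that line (camera adjusted p = 3.17e-14, over settings 3.17e-14 to 0.596). Cre recombinase itself rather than the mutant Idh1 allele cannot be told apart from it, because 0 arrays carry Cre and no mutant allele.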

How the results depend on the processing

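The threshold of 0.10 and the array weights were chosen after seeing the data, all other alternatives before. The fit without the line as a block called 82 genes against 0 and 67 probe sets against 0, and changed none of the calls of the 33 lists or of Idh1. With the line as a random block 241 genes were called, with the mean of probe sets 73, at an adjusted p under 0.10 it was 171, and with array weights 277 (119 higher, 158 lower), which gave line 2 the lowest weight, 0.448. Leaving out 1 line gave 0 to 1211 genes, the highest without line 2, where 1 residual degree of freedom is left and the pooled variance prior carries 5.80. Gene lists called were 8 after quantile normalization and 8 after cyclic loess, which added TGF-beta, heat shock and amino acid starvation genes, 0 with an estimated correlation, 2 with fry, and 6 to 11 with 1 line left out. Idh1 turned to -0.064 with line 8 exchanged, and ranged from -0.041 to 0.16 with 1 line left out. Genes that differed between lines were 0 with line 8 exchanged, 1 with the brightest probe set, and 0 to 37 with 1 line left out. Probe sets stayed at 0 in each such fit.

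Reversed values were, with line 8 exchanged, Sox2 at 0.035 and the immediate early list at -0.0034. With the brightest probe set they were Adamtsl3 at -0.0081, Nes at -0.029 and Ugt8a at 0.23. With 1 line left out, Nes ranged from -0.12 to 0.21 and Sox2 from -0.22 to 0.099, both reversed without line 7. Gfap ranged from -0.37 to 1.80, reversed without line 2. The oxidative phosphorylation median, 0.02 with all lines, ranged from -0.041 to 0.058, and without line 2 the direction of its test turned from down to up. The cause was not tested for any of these. Of the other values of named genes 588 stayed on their side of the threshold and 93 moved past it, and of the lists 550 stayed, 25 moved past it and 14 lost the call. With line 8 exchanged 35 genes had an unadjusted p under 0.01, and 0 of them were among the 999 found with the labels as given. All 999 had the same direction in all 3 lines, which an exchange of line 8 breaks for each of them. The lack of overlap therefore does not tell which labels are right. The median of all genes moved by less than 0.1 in every setting. Without detection calls, differences near background are not resolved.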

Other observations

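The genes below were chosen after their values were seen, as were the tests on Eif2s3y and the count of splits at the adjusted threshold, while the counts of splits at unadjusted p and for gene lists were planned.

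Several genes outside the fixed lists had the smallest adjusted p of the comparison (0.0669, limma). Their differences were nearly equal in the 3 lines, which a small p from 3 lines itself selects for. Ttyh1, a chloride channel family gene of neural stem cells, read -1.18 ± 0.07 (SE), Mfsd2a, a lysolipid transporter, -1.87 ± 0.12, Has2, a hyaluronan synthase, -2.60 ± 0.19, Pdpn, podoplanin, -1.58 ± 0.12, and Pak3, a kinase of neurons, -1.27 ± 0.10. Cntn1, a neural adhesion protein that binds Tnr, read -1.81 ± 0.15 and Myt1, a transcription factor of neural progenitors, -0.97 ± 0.09, with adjusted p of 0.0768 and 0.0864. None passed 0.05 with all 3 lines.

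Without line 2, where lines 7 and 8 alone were used, members of the fixed lists passed over all genes in both directions. None of the genes named in this paragraph passed with all 3 lines. Oligodendrocyte lineage genes that fell included Cnp (-0.72) and Sox10 (-0.57), and astrocyte genes that fell included Aqp4 (-1.90), which read -0.28 in line 2 and -1.36 with all 3 lines. Hes5, a Notch target of neural stem cells, fell by 0.74 on the log2 scale, and Tubb3 fell by 0.73, but in line 2 they read 0.33 and 0.03, and with all 3 lines -0.39 and -0.48. Sox10 read 0.43 in line 2 and -0.24 with all 3 lines. Spp1, osteopontin, rose by 1.60, Plk2, a p53 target, by 1.19, Peg10 by 1.04, Myc by 0.89 and Ccnd1, cyclin D1, by 0.68. With all 3 lines Spp1 read 1.01, Plk2 0.91, Peg10 0.72, Myc 0.63 and Ccnd1 0.16, and in line 2 Spp1 read -0.18 and Ccnd1 -0.87. Of 27 p53 targets 16 passed as higher and 0 as lower, and of 26 immediate early genes 13 passed as higher and 0 as lower. Some of those counted as higher were lower in line 2, among them Tnfrsf10b (-1.06), Spry4 (-1.80), Dusp6 (-1.70) and Etv5 (-0.55).

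Eif2s3y, a Y-linked translation factor gene, read 11.14 on the Ad-GFP array of line 2 and 6.69 on its Ad-Cre array, against 10.86 and 10.96 in line 8 and 5.55 and 5.58 in line 7. Loss of the whole Y chromosome is argued against by Kdm5d and Uty, the larger of whose differences was -0.40. A single failed probe set is argued against by 8 of 9 probe sets that fell by over 2 log2 units, and an exchange with a culture that expresses Xist by an Xist signal that differed by -7.11 from the lower line 7 array. No other biological explanation was tested.

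The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the adjusted threshold, a count that all 10 splits must reach, so that comparison shows nothing, and the highest other gave 233. At an unadjusted p under 0.05 it gave 2923 genes, 3 splits gave as many or more, and the highest other gave 3936. For gene lists it gave 5, 7 splits gave as many or more, and the highest other gave 11. With the line as a block, splits that part only the same pair repeat the same comparison. The 6 splits that part 1 pair thus come with repeated counts, and the 3 and 7 are not numbers of distinct comparisons. The 233 and 3936 genes come from 1 such comparison, which parts only the pair of line 2. It follows the line 2 Ad-Cre array, which points to a structure of these samples. Among the other 3 splits that part all 3 pairs, as the real one does, the highest unadjusted count was 742 and the highest list count 11. Each of these 3 exchanges the viruses of 1 line, and both highest counts came from the exchange in line 2.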
